A study of Homo sapiens with 12 samples.

How the data were processed

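The data were TT-seq libraries of nascent RNA from DLD-1 cells: a parental line with TIR1, a CNOT1-AID line and a CNOT4-AID line, each with 1 mM auxin for 2 h or 8 h and 15 minutes of 4-thiouridine, in 12 libraries (6 groups of 2). Titles and treatment labels gave both times and were used for grouping. The extract protocol speaks of 2 h only for this assay. Per the labels' protocols, labelled S. pombe RNA was added to the extracted RNA as a spike-in before capture, and libraries came from a stranded total RNA kit with rRNA depletion.

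The deposited values were whole-number counts per gene, with no normalization, in a table of 70455 rows: 63187 human, 7014 S. pombe and 254 whose identifiers begin with ENSRNA. Per the submitters' processing notes, STAR 2.5.1b, RSEM, SAMtools, featureCounts and DESeq2 and the builds hg38 and GRCh38 were used; which tool made the counts, the S. pombe reference and the strand setting of counting are not given in the sources used here. Without the strand setting, overlapping genes on opposite strands may share reads, and near-identical copies may lose or gain reads. All columns of values matched a sample (0 did not). S. pombe and ENSRNA rows were left out of human library sizes and tests.

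Human counts were filtered with filterByExpr (minimum count 10), which left 19916 genes, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, in a model with a mean per group over all 12 libraries. There were 9 contrasts: each tagged line against the parental line at each time, the tagged lines against each other at each time, the parental line over time, and the change over time in each tagged line minus that in the parental line. p-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Levels are CPM, computed from the deposited counts with TMM-scaled human library sizes. The biological coefficient of variation was 0.0365. The median SE of a log2 fold change was 0.13 in the CNOT1-AID line after 2 h. Libraries of 1 group correlated at 0.992 to 0.994 and other pairs at 0.931 to 0.986 (Pearson, log2 CPM, across genes). Same-group pairs differed by more than counting noise (lowest chi-square per degree of freedom 2.62), so no 2 libraries were counted as 1.

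The groups, contrasts, main tests, 40 gene lists and most alternatives were fixed before the data were examined. The lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry as alternatives, adjusted over the 40 lists within a contrast. They were CCR4-NOT subunits, other cytoplasmic mRNA decay factors, nuclear exosome, immediate early, NF-kB, p53, ATF4, unfolded protein response, heat shock, interferon-stimulated, aryl hydrocarbon receptor, NRF2, cholesterol, histone, G1/S, G2/M, RNA polymerase II, ribosome biogenesis, snoRNA and long non-coding host, transposon silencing, polycomb, Wnt, TGF-beta, YAP/TEAD, hypoxia, autophagy and colon identity genes. The rest were markers of fibroblasts, leukocytes, endothelium and neurons, germline genes, early embryonic genes, ZNF-numbered, ribosomal protein, mitochondrially encoded, respiratory chain, snoRNA, tRNA synthetase and proteasome genes.

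Named genes followed a rule: CNOT1, CNOT4 and the CCR4-NOT subunits; the 8 largest rises and 8 largest falls per contrast among genes past the threshold with a mean of at least 50 counts, an approved-style symbol and both libraries of one group beyond both of the other (not asked of the time effects in tagged lines); and up to 4 members with the smallest p from each list with a changed member or past camera. Y-linked genes and XIST were left out, the text omits some eligible genes, and some others are not reported here. Positions came from GENCODE release 29 (GRCh38) by Ensembl identifier, found for 18600 of 19916 genes. Of the tested genes 18 share a symbol with another row.

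A fold against a group with 0 counts was computed with a floor of 3 counts over the group and is a lower bound. Against 1 to 3 counts the ratio is given with an exact 95% interval. Ratios of human to S. pombe counts were compared by exact two-sided permutation tests, and gene classes by Fisher's exact test with adjustment over classes and contrasts. Shared responses were set beside 20 simulated draws of unchanged groups. Alternatives were DESeq2-style size factors, library size alone, S. pombe scaling, no filter, a minimum count of 50, protein-coding genes alone, no mitochondrial or small structural RNA genes, only the groups compared, an additive replicate block, limma-voom, the Wald test of DESeq2 1.42.0, an adjusted p of 0.01, a log2 fold change over 1 and leaving out each library. Without chromosome 11, without chromosome 19 ZNF genes and with split parental libraries were alternatives chosen after seeing the data. Groups of 2 allow no outlier test and no count over other splits.

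The count test was tested on simulated data for the CNOT1-AID line after 8 h against the parental line (19220 genes, 200 changed, 50 per fold size). It recovered 23 at 1.25-fold, 20 at 1.5-fold, 35 at 2-fold and 48 at 4-fold, and called 5 unchanged genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for other tests and figures.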

Results

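Newly made RNA was measured by transient transcriptome sequencing (TT-seq), in which cells take up the uridine analogue 4-thiouridine for a short time, here 15 minutes, and the labelled RNA is biotinylated, captured and sequenced. The cells were DLD-1, an established human colorectal adenocarcinoma line, in 3 forms: a parental line that carries the TIR1 auxin receptor and no tag, a line with an auxin-inducible degron (AID) on CNOT1, and a line with the degron on CNOT4. Auxin lets TIR1 mark a tagged protein for degradation. CNOT1 is the scaffold of CCR4-NOT, the main complex that shortens the poly(A) tails of mRNAs, and CNOT4 is a ubiquitin ligase associated with that complex. Each line was given 1 mM auxin for 2 h or 8 h, which made 6 groups of 2 libraries. Total counts ranged from 23419055 (parental, 2 h, replicate 1) to 33456108 (CNOT1-AID, 2 h, replicate 2). The study asked how nascent RNA synthesis changes when CNOT1 or CNOT4 is depleted. Every library came from auxin-treated cells, so a comparison of a tagged line with the parental line at the same time holds the depletion and any lasting difference between the lines together, whereas the change of that difference between 2 h and 8 h is free of a constant difference between lines. Protein levels were not analysed here. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

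The 2 targets were examined first. CNOT1 (ENSG00000125107, chromosome 16, 58519951 to 58629886, minus strand) was at 293.7 and 294.5 CPM (counts scaled to the normalized library size) in the parental line after 2 h, 269.8 and 273.4 in the CNOT1-AID line and 303.1 and 313.4 in the CNOT4-AID line. After 8 h CNOT1 was at 278.2 and 273.9 CPM in the parental line, 204.4 and 199.5 in the CNOT1-AID line and 272.0 and 276.7 in the CNOT4-AID line. CNOT4 (ENSG00000080802, chromosome 7, 135361795 to 135510127, minus strand) was at 208.1 and 218.4 CPM in the parental line after 2 h, 232.9 and 235.9 in the CNOT1-AID line and 237.1 and 228.6 in the CNOT4-AID line. After 8 h CNOT4 was at 214.1 and 213.4 CPM in the parental line, 272.5 and 294.9 in the CNOT1-AID line and 211.3 and 212.5 in the CNOT4-AID line. A degron acts on the protein, so these nascent RNA levels check the labels only weakly. Against the parental line, CNOT1 was −0.45 ± 0.04 in the CNOT1-AID line after 8 h (log2 fold change ± SE, edgeR adjusted p = 2.75e-12), and scaling to the spike-in put it at 0.10 (adjusted p = 0.479). CNOT4 rose by 0.41 ± 0.04 in the same comparison (adjusted p = 1.45e-10). In the CNOT4-AID line CNOT4 was 0.13 ± 0.04 (adjusted p = 0.022) after 2 h and −0.01 ± 0.04 (adjusted p = 0.865) after 8 h. The 2 h calls of both targets were weak. The CNOT1 value in the CNOT1-AID line (−0.12 ± 0.04, adjusted p = 0.0251) gave an adjusted p of 0.0655 to 0.134 with any of the 4 libraries left out. The CNOT4 value in the CNOT1-AID line (0.14 ± 0.04, adjusted p = 0.0134) gave 0.133 without parental replicate 1 and 0.0547 and 0.104 without CNOT1-AID replicates 1 and 2. The CNOT4 value in the CNOT4-AID line after 2 h gave 0.168 without parental replicate 1 and 0.207 without CNOT4-AID replicate 1, and scaling by library size alone put it at −0.03.

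Among the 12 CCR4-NOT subunits, all of them tested, 7 rose and 2 fell in the CNOT1-AID line after 2 h, and 6 rose and 3 fell after 8 h. In the CNOT4-AID line 6 rose and 0 fell after 2 h, and 2 rose and 1 fell after 8 h. Adjusted over the list alone, the counts were the same in all 4 comparisons. As a group the subunits did not pass the camera test (adjusted p = 0.168, 0.374, 0.281 and 0.847 in the same order). CNOT6L, a deadenylase subunit, rose in the CNOT1-AID line (0.57 ± 0.05 after 2 h and 0.64 ± 0.05 after 8 h). CNOT3 also rose there (0.34 ± 0.07 and 0.83 ± 0.07), with adjusted p of at most 0.00028 for the 4 values.

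The S. pombe spike-in gave a scale for total labelled RNA. Human counts per S. pombe count were 612 and 596 in the parental line after 2 h, 682 and 820 in the CNOT1-AID line and 814 and 948 in the CNOT4-AID line. After 8 h they were 683 and 705 in the parental line, 1005 and 998 in the CNOT1-AID line and 798 and 918 in the CNOT4-AID line. The tagged lines thus lay 1.24-fold (CNOT1-AID, 2 h), 1.46-fold (CNOT4-AID, 2 h), 1.44-fold (CNOT1-AID, 8 h) and 1.23-fold (CNOT4-AID, 8 h) above the parental line, and both tagged libraries exceeded both parental libraries each time (exact two-sided permutation p = 0.333, the smallest that 2 against 2 can give). The CNOT1-AID line was 0.851-fold the CNOT4-AID line after 2 h (exact permutation p = 0.667) and 1.17-fold after 8 h (exact permutation p = 0.333), and the parental line rose 1.149-fold between the times (exact permutation p = 0.333). The spike-in RNA was mixed with extracted RNA, so the ratio is per amount of RNA and not per cell. Genes of the mitochondrial genome took 10.9% ± 0.848 (SD, n = 2) of human counts in the parental line after 2 h and 16.9% ± 1.40 in the CNOT1-AID line after 8 h, the extremes of the groups.

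**Figure D1:**
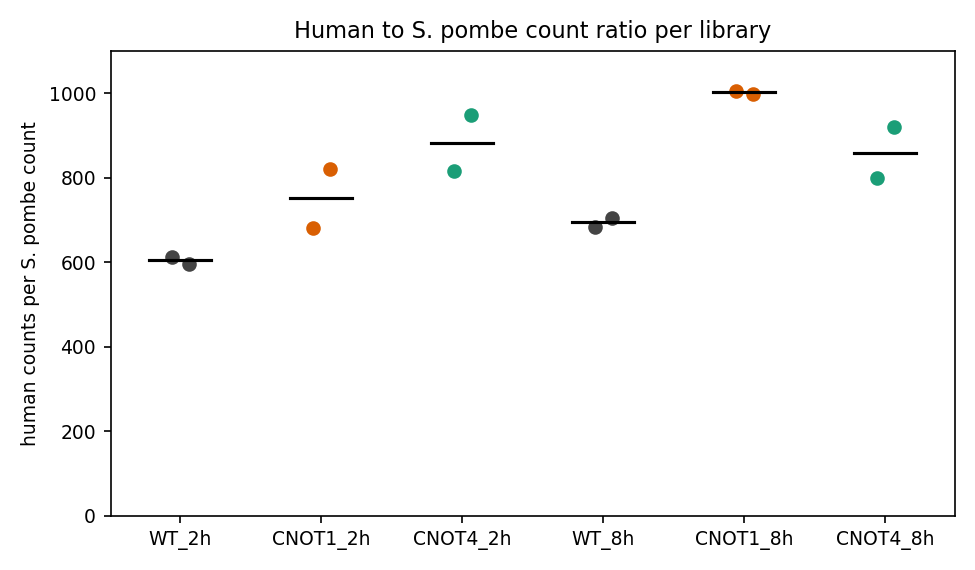
Human counts per S. pombe spike-in count (vertical axis, a ratio of counts) for the 12 libraries in 6 groups; points are libraries and lines are group means. The tagged groups average 751 and 881 after 2 h and 1002 and 858 after 8 h, against 604 and 694 in the parental line.

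Fold changes below are relative to the typical gene of each comparison, since the trimmed mean of M-values (TMM) scaling holds that gene near 0. Scaling to S. pombe counts moved the median of all genes to 0.22 (CNOT1-AID, 2 h), 0.37 (CNOT4-AID, 2 h), 0.54 (CNOT1-AID, 8 h) and 0.27 (CNOT4-AID, 8 h) on the log2 scale. It moved the median to 0.20 for the parental line between the times, to −0.15 and 0.27 for the CNOT1-AID line against the CNOT4-AID line after 2 h and 8 h, and to 0.33 for the time effect in the CNOT1-AID line. Scaling by library size alone moved it to −0.17 (CNOT4-AID, 2 h), 0.12 (time effect, CNOT1-AID) and 0.14 (time effect, CNOT4-AID). A value after a gene name is its log2 fold change ± SE from 2 libraries per group, and each comparison states the largest adjusted p among its named genes. Histone genes, ribosomal protein genes, MT-RNR2, DUXAP9 and many zinc finger genes have near-identical copies or pseudogenes that counting could confuse, and ZNF571 and ZNF540 overlap on opposite strands, so single values of these genes are uncertain.

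In the CNOT1-AID line after 2 h, many zinc finger genes of chromosome 19 were lower, some of them almost silent, and Wnt targets were higher as a list than in the parental line. The lists of immediate early genes and of the mitochondrial genome were higher and that of mitotic genes lower with the preset correlation of camera, but not with an estimated one (adjusted p = 0.57, 0.57 and 0.241). ZNF471 (ENSG00000196263, chromosome 19, 56507843 to 56530221, plus strand) had 8.27 ± 1.04 CPM (SD, n = 2) in the parental line and 0 counts in the CNOT1-AID line, at least 164-fold lower with a floor of 3 counts over the group. ZNF708 was at 47.6 ± 2.65 and 0.0336 ± 0.00366 CPM, a ratio of 1432 (95% interval 395.9 to 11830), and ZNF649 was lower by a ratio of 1249 (345.3 to 10320). KLHL4, a kelch family gene (ENSG00000102271, chromosome X, 87517749 to 87670050, plus strand), was at 23.01 ± 1.57 CPM in the CNOT1-AID line and 0.0207 ± 0.0292 CPM in the parental line, a ratio of 1209 (216.7 to 47800). The gastric mucin gene MUC5AC (4.61 ± 0.12), the kinase gene WNK2 (5.37 ± 0.14) and DUXAP9, a long non-coding RNA (7.48 ± 0.27), were also far higher. Intervals and floors in this text cover counting error only. Of 19916 genes tested, 3842 were higher and 3669 lower. With S. pombe scaling 4861 were higher and 1061 lower, and with library size alone 2595 and 4977.

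By fixed list, 55 of 386 ZNF-numbered genes rose and 169 fell in the CNOT1-AID line after 2 h, with a median of −0.16 that S. pombe scaling turned to 0.07 (camera adjusted p = 4.35e-34, and adjusted p = 0.0431 with an estimated correlation). The falls lay mainly on chromosome 19, where 114 of 169 fell (median −1.13), against 55 of 217 elsewhere, where the list no longer passed (adjusted p = 0.0535). ZNF571 (−6.86 ± 0.09), ZNF540 (−8.37 ± 0.11) and ZNF431 (−4.92 ± 0.07) still had reads. Of 20 Wnt/beta-catenin targets 13 rose and 1 fell (median 0.27, adjusted p = 2.31e-10, and adjusted p = 0.0431 with an estimated correlation). These included CD44 (2.01 ± 0.06) and the stem cell receptor gene LGR5 (1.04 ± 0.05). Of 38 immediate early genes 25 rose and 6 fell (median 0.35, adjusted p = 1e-06, but adjusted p = 0.57 with an estimated correlation), among them EGR1 (1.95 ± 0.06) and FOSB (2.08 ± 0.15). All but 3 of 37 mitochondrially encoded genes rose and 0 fell (median 0.66, adjusted p = 9.99e-09, but 0.57 with an estimated correlation). Of 43 G2/M genes 1 rose and 34 fell (median −0.29, adjusted p = 3.82e-08, but adjusted p = 0.241 with an estimated correlation), among them BORA (−0.69 ± 0.06). Ribosome biogenesis genes rose in 28 of 50 cases and fell in 1 (median 0.15, adjusted p = 0.002, but adjusted p = 0.643 with an estimated correlation), among them NOLC1 (0.36 ± 0.05). With library size alone that list had an adjusted p of 0.0524. The counts higher and lower adjusted over the list alone were 60 and 175 (ZNF), 13 and 1 (Wnt), 26 and 6 (immediate early), 36 and 0 (mitochondrial), 1 and 36 (G2/M) and 28 and 1 (ribosome biogenesis). The largest edgeR adjusted p of a gene named in this comparison was 5.8e-08 (NOLC1).

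**Figure D2:**
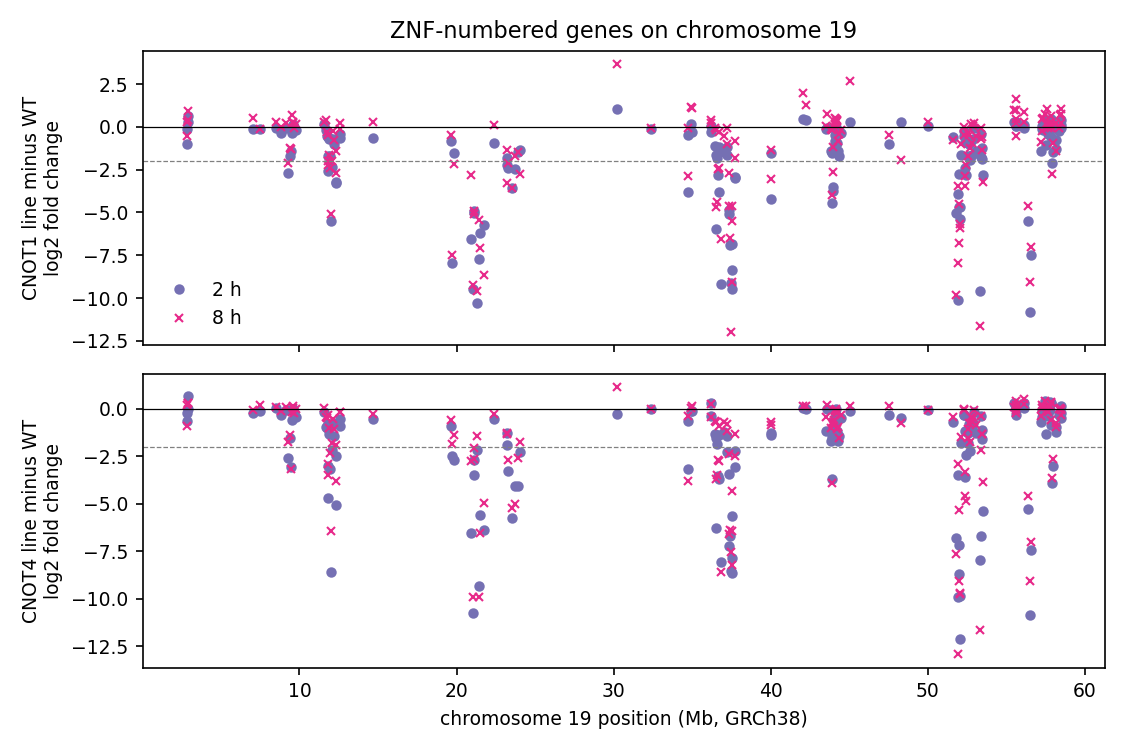
Fitted log2 fold change against the parental line (vertical axis) of the tested ZNF-numbered genes of chromosome 19 by position (horizontal axis, Mb) in the tagged lines; each point is a gene and the dashed line marks 4-fold lower. Of the 169 genes 114 fell in the CNOT1-AID line and 123 in the CNOT4-AID line after 2 h, and genes with 0 counts stand at fitted values that depend on the prior count and are no bound.

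Many zinc finger genes of chromosome 19 were lower in the CNOT4-AID line after 2 h too, and 48 of 169 were over 4-fold lower in both tagged lines. Its colon epithelial genes were lower as a list than in the parental line. YAP/TEAD targets were higher and replication-dependent histone genes lower with the preset correlation, but not with an estimated one (camera adjusted p = 0.0541 and 0.532). CBLIF, the gastric intrinsic factor gene (ENSG00000134812, chromosome 11, 59829268 to 59845501, minus strand), was at 23.4 ± 0.689 CPM (SD, n = 2) against 0.0178 ± 0.0251 CPM, a ratio of 1223 (219.1 to 48360). The long non-coding RNA EPIC1 (ENSG00000224271, chromosome 22, 47631674 to 47855600, plus strand) was at 64.1 ± 5.43 against 0.751 ± 0.244 CPM, and the homeobox gene HOXD10 (6.13 ± 0.23) and the surface glycoprotein gene PROM1 (5.61 ± 0.28) were also higher. ZNF614 fell from 19.9 ± 2.72 CPM to 0 counts, at least 335.6-fold lower with the same floor, ZNF471 was at least 137.6-fold lower, and ZNF430 was lower by a ratio of 1840 (629.3 to 8926). Of 19916 genes 3842 were higher and 3673 lower. With S. pombe scaling 8358 were higher and 1062 lower, and with library size alone 2101 and 6546. Leaving out chromosome 11, an alternative chosen after seeing the data, left 6906 changed genes.

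Chromosome 11 stood apart in this line. Its 795 tested protein-coding genes had a median log2 fold change of 0.396 (bootstrap 95% interval 0.355 to 0.43) after 2 h and 0.394 after 8 h, against −0.002 and −0.022 for genes of other chromosomes. On the short arm the median was 0.265 and 0.285 (263 genes), and on the long arm 0.444 and 0.439 (532 genes). In the CNOT1-AID line the chromosome 11 medians were 0.068 and 0.15. The change of the CNOT4-AID difference from 2 h to 8 h had a median of −0.011. Of the lists that passed in this line, those of colon identity, histone, TGF-beta and mitochondrially encoded genes have no member on chromosome 11, whereas 6 ZNF-numbered genes and 1 member each of the ribosome biogenesis, ATF4 and immediate early lists lie there.

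**Figure D3:**
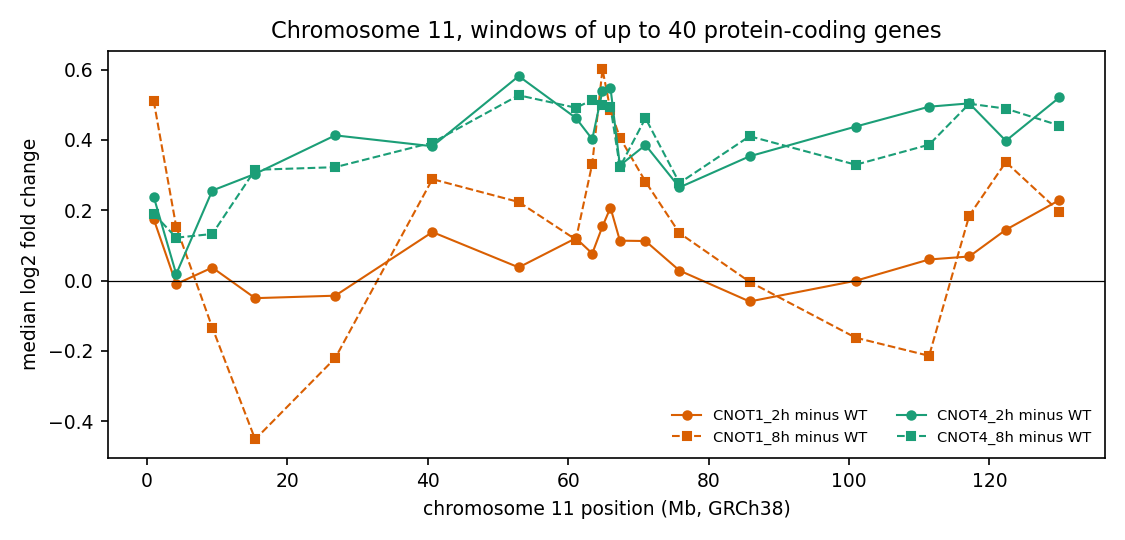
Median log2 fold change against the parental line (vertical axis) in 20 consecutive windows of up to 40 protein-coding genes along chromosome 11 (horizontal axis, Mb), for both tagged lines and times. The CNOT4-AID medians range from 0.02 to 0.58 after 2 h and from 0.12 to 0.53 after 8 h, whereas those of the CNOT1-AID line range from −0.06 to 0.23 and from −0.45 to 0.60.

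Among the fixed lists, 14 of 18 YAP/TEAD targets rose and 0 fell in the CNOT4-AID line after 2 h (median 0.67, camera adjusted p = 3.68e-12, but adjusted p = 0.0541 with an estimated correlation). They included DLC1 (1.61 ± 0.05), the matricellular gene CCN1 (1.21 ± 0.05) and TGFB2 (0.82 ± 0.04), and 3 members lie on chromosome 11. Of 21 colon epithelial and DLD-1 identity genes 2 rose and 16 fell (median −0.58, adjusted p = 1.01e-10, and adjusted p = 0.0116 with an estimated correlation), among them the cadherin gene CDH17 (−1.53 ± 0.07) and VIL1, which encodes villin of the brush border (−2.79 ± 0.16). Of 39 replication-dependent histone genes 0 rose and 36 fell (median −0.50, adjusted p = 4.41e-10, but adjusted p = 0.532 with an estimated correlation), for example H2AC14 (−0.86 ± 0.07), H3C12 (−0.92 ± 0.07) and H2BC14 (−1.32 ± 0.13). Of the ZNF-numbered genes 44 rose and 191 fell, with a median of −0.30 that S. pombe scaling turned to 0.09 (adjusted p = 1.63e-29, and adjusted p = 0.0461 with an estimated correlation). On chromosome 19, 123 of 169 fell (median −1.22), and elsewhere 36 of 217 rose and 68 fell (median −0.06, adjusted p = 0.00822). Mitochondrially encoded genes rose in 28 of 37 cases and fell in 0 (median 0.45, adjusted p = 1.18e-05, but 0.553 with an estimated correlation).

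Further lists were higher in the CNOT4-AID line after 2 h with the preset correlation of camera, several of them with members on chromosome 11, whose genes were higher as a whole. Of 20 Wnt/beta-catenin targets 9 rose and 6 fell (median 0.17, adjusted p = 0.000111, but adjusted p = 0.17 with an estimated correlation and 0.477 without the 3 members on chromosome 11). CD44, on chromosome 11, went from 28.25 ± 2.15 to 500.4 ± 14.9 CPM (4.14 ± 0.05), and PROX1 fell (−0.96 ± 0.09). Of 22 targets of the oxidative stress factor NRF2, 11 rose and 2 fell (median 0.27, adjusted p = 0.00943, but adjusted p = 0.318 with an estimated correlation and 0.0529 with library size alone). NQO1, a quinone reductase gene, was among them (1.36 ± 0.08), and 2 members lie on chromosome 11. Ribosome biogenesis genes rose in 30 of 50 cases and fell in 1 (median 0.18, adjusted p = 0.00249, but adjusted p = 0.553 with an estimated correlation and 0.226 with library size alone). Of 18 TGF-beta and SMAD targets 9 rose and 4 fell, with a median of 0.13 that library size alone turned to −0.03 (adjusted p = 0.0195, but adjusted p = 0.553 with an estimated correlation, 0.0529 with library size alone and 0.09 without CNOT4-AID replicate 1). Of 24 hypoxia and glycolysis genes 12 rose and 4 fell, with a median of 0.12 that library size alone turned to −0.04 (adjusted p = 0.0311, but adjusted p = 0.424 with an estimated correlation, 0.276 with library size alone, 0.178 without the 2 members on chromosome 11 and 0.0656 without CNOT4-AID replicate 1). Of 77 cytosolic ribosomal protein genes 27 rose and 0 fell, with a median of 0.10 that library size alone turned to −0.06 (adjusted p = 0.0317, but adjusted p = 0.884 with an estimated correlation). That call also ended with library size alone (0.814), with fry (0.0511), without the 6 members on chromosome 11 (0.211), without parental replicate 2 (0.0926) and without CNOT4-AID replicate 1 (0.358). Adjusted over the list alone, the counts higher and lower were 14 and 0 (YAP/TEAD), 2 and 16 (colon), 0 and 37 (histones), 49 and 196 (ZNF), 28 and 0 (mitochondrial), 10 and 6 (Wnt), 12 and 2 (NRF2), 31 and 1 (ribosome biogenesis), 9 and 4 (TGF-beta), 13 and 4 (hypoxia) and 27 and 0 (ribosomal proteins). Of the genes named in this comparison, H2BC14 had the largest edgeR adjusted p (4.85e-11).

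The CNOT1-AID line after 8 h differed from the parental line in more genes than any other comparison: 6608 were higher and 6711 lower. As lists, RNA polymerase II genes were higher, and genes of DNA replication and colon identity were lower. Ribosome biogenesis and heat shock genes were higher and YAP/TEAD and ATF4 targets lower with the preset correlation, but not with an estimated one (camera adjusted p = 0.097, 0.0889, 0.124 and 0.483), and S. pombe scaling turned the ATF4 median to 0.07. E2F2, a transcription factor gene of the G1/S transition (ENSG00000007968, chromosome 1, 23506430 to 23531220, minus strand), was at 8.73 ± 0.931 CPM (SD, n = 2) against 46.4 ± 0.0313 CPM. TSPAN8, a tetraspanin gene of colon epithelium (ENSG00000127324, chromosome 12, 71125085 to 71441898, minus strand), was at 3.14 ± 0.133 against 61.3 ± 5.63 CPM. UBTF (ENSG00000108312, chromosome 17, 44205033 to 44221626, minus strand) was at 169 ± 4.55 against 65.6 ± 0.671 CPM. The largest rises included DUXAP9, with a ratio of 877.5 (157.1 to 34700), and KLHL4 (8.14 ± 0.23). ZNF570 and ZNF845 had 0 counts in the CNOT1-AID line, at least 347.3-fold and 279-fold lower. With S. pombe scaling 10697 genes were higher and 2879 lower.

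Of 50 ribosome biogenesis genes 48 rose and 0 fell in the CNOT1-AID line after 8 h (median 0.56, camera adjusted p = 5.24e-13, but adjusted p = 0.097 with an estimated correlation), among them UBTF (1.37 ± 0.05), RRS1 (1.59 ± 0.07) and NOB1 (0.98 ± 0.05). Of 43 G1/S and DNA replication genes 3 rose and 37 fell (median −0.69, adjusted p = 1.02e-10, and adjusted p = 0.0226 with an estimated correlation), among them E2F2 (−2.40 ± 0.08) and the DNA polymerase gene POLA1 (−1.34 ± 0.05). Of 21 colon identity genes 2 rose and 16 fell (median −0.71, adjusted p = 1.02e-06, and adjusted p = 0.0226 with an estimated correlation), among them TSPAN8 (−4.28 ± 0.10), the keratin gene KRT20 (−4.09 ± 0.15) and the splicing regulator gene ESRP1 (−1.40 ± 0.05). RNA polymerase II subunits and elongation factors rose in 28 of 40 cases and fell in 4 (median 0.38, adjusted p = 0.000209, and adjusted p = 0.0461 with an estimated correlation), among them HEXIM1, an inhibitor of P-TEFb (1.63 ± 0.06), and POLR2A, the largest subunit (1.09 ± 0.05). YAP/TEAD targets fell in 13 of 18 cases and rose in 3 (median −0.94, adjusted p = 2.98e-06, but adjusted p = 0.124 with an estimated correlation), among them DLC1 (−2.36 ± 0.06) and the ectonucleotidase gene NT5E (−2.57 ± 0.08). Heat shock genes rose in 15 of 19 cases and fell in 0 (median 0.66, adjusted p = 5.16e-06, but adjusted p = 0.0889 with an estimated correlation), among them the chaperone genes HSPB1 (1.06 ± 0.05) and HSPA8 (1.00 ± 0.05). Of 24 cholesterol biosynthesis genes 4 rose and 19 fell (median −0.75, adjusted p = 5.04e-05, but adjusted p = 0.166 with an estimated correlation), among them HMGCS1 (−1.47 ± 0.05). Of 25 ATF4 and amino acid stress targets 2 rose and 18 fell (median −0.48, adjusted p = 5.04e-05, but adjusted p = 0.483 with an estimated correlation), among them SLC7A11 (−2.81 ± 0.07) and PHGDH of serine synthesis (−1.35 ± 0.05).

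In the same comparison, mitochondrially encoded genes rose in 35 of 37 cases and fell in 0 (median 0.64, adjusted p = 0.000187, but adjusted p = 0.64 with an estimated correlation). Non-coding host genes, a list of host genes of small nucleolar RNAs with other long non-coding RNAs, rose in 13 of 21 cases and fell in 2 (median 0.30, adjusted p = 0.00488, but adjusted p = 0.418 with an estimated correlation), among them MALAT1 (1.34 ± 0.05). G2/M genes fell in 29 of 43 cases and rose in 8, with a median of −0.31 that S. pombe scaling turned to 0.24 (adjusted p = 0.00583, but adjusted p = 0.483 with an estimated correlation), among them ECT2 (−1.57 ± 0.05). Cytosolic tRNA synthetase genes fell in 12 of 20 cases and rose in 7, with a median of −0.31 that S. pombe scaling turned to 0.24 (adjusted p = 0.0395, but adjusted p = 0.69 with an estimated correlation). That call ended without parental replicate 1 (0.0688) or CNOT1-AID replicate 2 (0.0581) and with library size alone (0.0524). Histone genes rose in 24 of 39 cases and fell in 5 (median 0.24, adjusted p = 0.0445, but adjusted p = 0.799 with an estimated correlation), a call that ended without parental replicate 1 (0.0762) or CNOT1-AID replicate 2 (0.0998). H2BC14 was 1.45 ± 0.10. TGF-beta and SMAD targets fell in 12 of 18 cases and rose in 3 (median −0.77, adjusted p = 0.0491, but adjusted p = 0.682 with an estimated correlation), which ended without parental replicate 2 (0.0621) or CNOT1-AID replicate 2 (0.0556), with library size alone (0.0524) and with DESeq2-style size factors (0.05). The counts higher and lower adjusted over the list alone were 48 and 0 (ribosome biogenesis), 4 and 37 (G1/S), 2 and 16 (colon), 28 and 4 (RNA polymerase II), 3 and 13 (YAP/TEAD), 15 and 0 (heat shock), 4 and 19 (cholesterol), 2 and 18 (ATF4), 35 and 0 (mitochondrial), 13 and 2 (non-coding hosts), 8 and 29 (G2/M), 7 and 13 (tRNA synthetases), 24 and 5 (histones) and 3 and 12 (TGF-beta). The largest edgeR adjusted p of a gene named in this comparison was 6.04e-16 (H2BC14).

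In the CNOT4-AID line after 8 h colon identity genes were lower as a list than in the parental line. Zinc finger and histone genes were lower and mitochondrially encoded genes higher with the preset correlation, but not with an estimated one (camera adjusted p = 0.0861, 0.652 and 0.718), and S. pombe scaling turned the zinc finger median to 0.16. CBLIF was at 19.5 ± 0.586 CPM (SD, n = 2) against 0.0184 ± 0.026 CPM, a ratio of 1092 (195.7 to 43190), EPIC1 was at 68.5 ± 2.36 against 0.479 ± 0.106 CPM, and HOXD10 was at 20.4 ± 0.194 against 0.669 ± 0.375 CPM. ZNF649 had 0 counts, at least 647.7-fold lower, ZNF845 was at least 265.6-fold lower, and ZNF493 was lower by a ratio of 1217 (218.1 to 48120). In all, 3243 genes were higher and 3582 lower. With S. pombe scaling 5303 were higher and 976 lower. Without chromosome 11, whose genes were higher in this line, 6042 genes changed.

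Of 21 colon identity genes 0 rose and 16 fell in the CNOT4-AID line after 8 h (median −0.63, camera adjusted p = 1.02e-15, and adjusted p = 0.00374 with an estimated correlation), among them VIL1 (−3.60 ± 0.19), TSPAN8 (−1.51 ± 0.07) and the keratin gene KRT8 (−0.80 ± 0.04). ZNF-numbered genes fell in 162 of 386 cases and rose in 49 (median −0.11, adjusted p = 5.31e-20, but adjusted p = 0.0861 with an estimated correlation and 0.121 outside chromosome 19). Histone genes fell in 34 of 39 cases and rose in 0 (median −0.45, adjusted p = 1.57e-09, but 0.652 with an estimated correlation). Mitochondrially encoded genes rose in 29 of 37 cases and fell in 0 (median 0.42, adjusted p = 1.97e-06, but 0.718 with an estimated correlation). Wnt/beta-catenin targets rose in 10 of 20 cases and fell in 5 (median 0.26, adjusted p = 2.45e-06, but adjusted p = 0.0994 with an estimated correlation and 0.109 without the 3 members on chromosome 11), with CD44 at 3.45 ± 0.06. ATF4 and amino acid stress targets rose in 20 of 25 cases and fell in 1 (median 0.29, adjusted p = 8.27e-05, but adjusted p = 0.652 with an estimated correlation), among them PHGDH (0.46 ± 0.04) and SLC3A2, on chromosome 11 (0.75 ± 0.04). YAP/TEAD targets rose in 8 of 18 cases and fell in 2, with a median of 0.02 that library size alone turned to −0.02 (adjusted p = 0.0211, but adjusted p = 0.652 with an estimated correlation and 0.285 without the 3 members on chromosome 11). Immediate early genes rose in 19 of 38 cases and fell in 8 (median 0.30, adjusted p = 0.0228, but adjusted p = 0.907 with an estimated correlation). That call ended without CNOT4-AID replicate 1 (0.0864) or without its chromosome 11 member (0.0938). TGF-beta and SMAD targets rose in 9 of 18 cases and fell in 2 (median 0.14, adjusted p = 0.0235, but adjusted p = 0.883 with an estimated correlation), among them ATOH8 (3.29 ± 0.15). Adjusted over the list alone, the counts higher and lower were 1 and 17 (colon), 58 and 167 (ZNF), 0 and 34 (histones), 31 and 0 (mitochondrial), 11 and 5 (Wnt), 22 and 1 (ATF4), 8 and 2 (YAP/TEAD), 20 and 8 (immediate early) and 9 and 2 (TGF-beta). Of the genes named in this comparison, PHGDH had the largest edgeR adjusted p (2.78e-11).

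**Figure D4:**
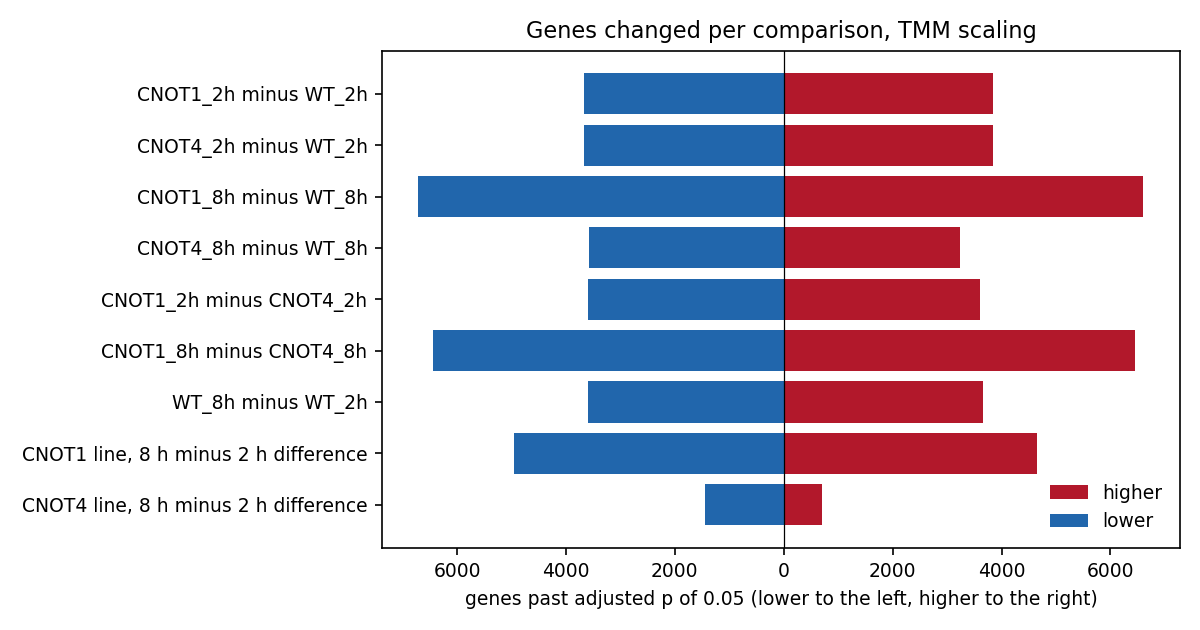
Number of genes higher (right) and lower (left) at an adjusted p of 0.05 in each of the 9 comparisons (horizontal axis, genes; edgeR quasi-likelihood test, TMM scaling). The bars of the CNOT1-AID line after 8 h reach 6608 higher and 6711 lower, and those of the time effect in the CNOT4-AID line reach 694 and 1446.

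The tagged lines were then set against each other, which tests how they differ without the parental libraries. After 2 h, colon identity genes were higher as a list in the CNOT1-AID line than in the CNOT4-AID line. The lists of YAP/TEAD, mitotic, cholesterol and ribosomal protein genes were lower with the preset correlation, but not with an estimated one (camera adjusted p = 0.0678, 0.217, 0.61 and 0.936), and those of histone and immediate early genes were higher on the same terms (0.87 and 0.936). CBLIF had 0 counts in the CNOT1-AID line, at least 467-fold lower, whereas KLHL4 (5.36 ± 0.18) and the mucin gene MUC6 (5.06 ± 0.45) were higher. In all 3614 genes were higher and 3604 lower. S. pombe scaling gave 1326 and 3340, and library size alone 4655 and 2726. Colon identity genes were higher in 16 of 21 cases and lower in 2 (median 0.59, camera adjusted p = 9.49e-13, and adjusted p = 0.0068 with an estimated correlation), but KRT20 was lower (−3.26 ± 0.12). YAP/TEAD targets were higher in 1 and lower in 12 of 18 cases (median −0.46, adjusted p = 9.39e-14, but 0.0678 with an estimated correlation). G2/M genes were lower in 35 of 43 cases and higher in 0 (median −0.30, adjusted p = 6.92e-08, but 0.217 with an estimated correlation). Histone genes were higher in 33 and lower in 2 of 39 cases (median 0.42, adjusted p = 5.72e-07, but 0.87 with an estimated correlation). Ribosomal protein genes were lower in 35 of 77 cases and higher in 0 (median −0.11, adjusted p = 0.000644, but adjusted p = 0.936 with an estimated correlation and 0.0524 without CNOT4-AID replicate 1). Cholesterol biosynthesis genes were higher in 2 and lower in 16 of 24 cases (median −0.30, adjusted p = 0.00153, but adjusted p = 0.61 with an estimated correlation). Immediate early genes were higher in 21 and lower in 9 of 38 cases (median 0.33, adjusted p = 0.0236, but adjusted p = 0.936 with an estimated correlation and 0.134 without CNOT4-AID replicate 2). The tRNA synthetase genes were lower in 12 of 20 cases and higher in 0 (median −0.17, adjusted p = 0.0272, but adjusted p = 0.936 with an estimated correlation). That call ended without CNOT1-AID replicate 1 (0.0583), CNOT4-AID replicate 2 (0.057), the chromosome 11 member (0.0606) or with library size alone (0.135). The counts higher and lower adjusted over the list alone were 17 and 2 (colon), 1 and 14 (YAP/TEAD), 0 and 35 (G2/M), 33 and 2 (histones), 0 and 37 (ribosomal proteins), 2 and 17 (cholesterol), 24 and 9 (immediate early) and 0 and 12 (tRNA synthetases). The largest edgeR adjusted p of a gene named in this comparison was 3.13e-12 (MUC6).

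After 8 h, 6443 genes were higher and 6446 lower in the CNOT1-AID line than in the CNOT4-AID line, and 7976 and 3730 with S. pombe scaling. With the preset correlation of camera, the lists of ATF4, YAP/TEAD, DNA replication and cholesterol genes were lower, and those of ribosome biogenesis, histone, heat shock and zinc finger genes were higher. With an estimated correlation 0 lists passed (adjusted p = 0.0717 to 0.418 for these lists). SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349, minus strand) was at 37.7 ± 2.30 against 396 ± 3.86 CPM (SD, n = 2), and DLC1 (ENSG00000164741, chromosome 8, 13083361 to 13604610, minus strand) at 22.1 ± 1.39 against 207 ± 1.27 CPM. CBLIF was lower by a ratio of 1130 (202.5 to 44690) and the hedgehog inhibitor gene HHIP by 221 (75.27 to 1074), while DACH1 was higher by 155.1 (42.61 to 1286). ATF4 targets were lower in 21 of 25 cases and higher in 1 (median −0.83, camera adjusted p = 4.69e-11, but adjusted p = 0.185 with an estimated correlation), with PHGDH at −1.81 ± 0.05. YAP/TEAD targets were lower in 16 and higher in 1 of 18 (median −0.99, adjusted p = 4.69e-11, but 0.0721 with an estimated correlation). Ribosome biogenesis genes were higher in 44 and lower in 1 of 50 (median 0.52, adjusted p = 1.71e-10, but 0.171 with an estimated correlation). G1/S genes were higher in 3 and lower in 36 of 43 (median −0.73, adjusted p = 5.41e-10, but 0.0717 with an estimated correlation). Histone genes were higher in 36 of 39 and lower in 0 (median 0.62, adjusted p = 3.56e-09, but adjusted p = 0.418 with an estimated correlation), with H2BC14 at 3.00 ± 0.12. Heat shock genes were higher in 16 of 19 and lower in 0 (median 0.65, adjusted p = 8.69e-08, but 0.0721 with an estimated correlation). Cholesterol genes were higher in 3 and lower in 19 of 24 (median −0.72, adjusted p = 3.05e-05, but 0.171 with an estimated correlation). ZNF-numbered genes were higher in 217 and lower in 56 of 386 (median 0.37, adjusted p = 0.000125, but 0.411 with an estimated correlation). TGF-beta targets were higher in 2 and lower in 15 of 18 (median −1.04, adjusted p = 0.000169, but 0.411 with an estimated correlation). Synthetase genes of tRNA were higher in 6 and lower in 12 of 20 (median −0.50, adjusted p = 0.00054, but 0.418 with estimated correlation). Immediate early genes were higher in 12 and lower in 21 of 38 (median −0.36, adjusted p = 0.00202, but adjusted p = 0.547 with an estimated correlation), with ATF3 at −4.60 ± 0.14. RNA polymerase II genes were higher in 26 and lower in 5 of 40 (median 0.32, adjusted p = 0.0028, but adjusted p = 0.102 with an estimated correlation). G2/M genes were higher in 7 and lower in 29 of 43 (median −0.31) and non-coding host genes higher in 11 and lower in 2 of 21 (median 0.25), each with an adjusted p of 0.0103, but adjusted p = 0.418 with an estimated correlation. Wnt targets were higher in 9 and lower in 9 of 20, with a median of 0.04, a mean of −0.17 and a test that pointed lower (adjusted p = 0.0388, but adjusted p = 0.418 with an estimated correlation), which ended without CNOT1-AID replicate 2 (0.0698), without the chromosome 11 members (0.216) and with library size alone (0.0667). Adjusted over the list alone, the counts were the same except 219 and 56 for ZNF-numbered and 13 and 21 for immediate early genes. Of the genes named in this comparison, DACH1 had the largest edgeR adjusted p (3.76e-17).

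In the parental line itself, the comparison of 8 h with 2 h gives the background of auxin and culture time. With the preset correlation of camera, the targets of the aryl hydrocarbon receptor, a sensor of aromatic compounds, were lower as a list after 8 h, and ATF4, unfolded protein response and cholesterol genes were higher. Estimating the correlation left 0 lists past the threshold (adjusted p = 0.0563 for the receptor targets and 0.132 for the other lists named). CYP1A1, a detoxifying enzyme gene and receptor target (ENSG00000140465, chromosome 15, 74719542 to 74725610, minus strand), went from 56.3 ± 3.13 to 2.31 ± 0.256 CPM (SD, n = 2) and TIPARP from 361.5 ± 54.8 to 77.3 ± 1.41 CPM. EGR1 rose by 2.32 ± 0.06, and the stress factor gene DDIT3 went from 1.67 ± 0.205 to 9.05 ± 0.655 CPM. In all 3664 genes were higher and 3589 lower, and with S. pombe scaling 3990 and 531. All 10 aryl hydrocarbon receptor targets fell (median −0.82, camera adjusted p = 1.02e-21, but 0.0563 with an estimated correlation). G2/M genes fell in 34 of 43 cases and rose in 0 (median −0.32, adjusted p = 9.62e-14, but 0.0666 with an estimated correlation). PLK1 was −0.76 ± 0.06. YAP/TEAD targets fell in 13 and rose in 2 of 18 (median −0.52, adjusted p = 9.62e-14, but 0.0598 with an estimated correlation). ATF4 targets rose in 18 and fell in 4 of 25 (median 0.46, adjusted p = 9.27e-13), unfolded protein response genes rose in 15 and fell in 1 of 20 (median 0.37, adjusted p = 1.04e-08), and cholesterol genes rose in 16 and fell in 1 of 24 (median 0.38, adjusted p = 9.54e-07), but each had adjusted p = 0.132 with an estimated correlation. Ribosome biogenesis genes fell in 39 of 50 and rose in 0 (median −0.23, adjusted p = 6.78e-09) and non-coding host genes fell in 14 of 21 and rose in 0 (median −0.29, adjusted p = 9.78e-07), again with adjusted p = 0.132 with an estimated correlation. Ribosomal protein genes fell in 56 of 77 and rose in 0 (median −0.20, adjusted p = 2.19e-09, but 0.428 with an estimated correlation). Histone genes fell in 27 and rose in 1 of 39 (median −0.29, adjusted p = 9.54e-07, but 0.45 with an estimated correlation). Immediate early genes fell in 21 and rose in 6 of 38 (median −0.35, adjusted p = 9.54e-07, but 0.308 with an estimated correlation). The tRNA synthetase genes rose in 12 and fell in 3 of 20 (median 0.20, adjusted p = 0.000724, but 0.409 with an estimated correlation). TGF-beta targets rose in 6 and fell in 8 of 18 (median −0.32, adjusted p = 0.00111, but 0.347 with an estimated correlation). Mitochondrially encoded genes rose in 16 of 37 and fell in 0 (median 0.23, adjusted p = 0.00199, but 0.609 with an estimated correlation). S. pombe scaling turned the medians of the remaining lists positive. These were proteasome genes (13 of 34 fell, 1 rose, median −0.12 to 0.07, adjusted p = 0.0128), other mRNA decay factors (17 of 44 fell, 7 rose, median −0.08 to 0.11, adjusted p = 0.0203) and RNA polymerase II genes (16 of 40 fell, 2 rose, median −0.13 to 0.06, adjusted p = 0.026), each with adjusted p = 0.132 with an estimated correlation. The last was respiratory chain genes (15 of 66 fell, 0 rose, median −0.10 to 0.10, adjusted p = 0.0486, but adjusted p = 0.294 with an estimated correlation), which ended without parental 2 h replicate 1 (0.181) or 8 h replicate 2 (0.0708). Counts adjusted over the list alone, higher and lower, differed for YAP/TEAD (2 and 14), ribosomal proteins (0 and 62), ribosome biogenesis (0 and 40), histones (1 and 29), cholesterol (17 and 1), non-coding hosts (0 and 16), tRNA synthetases (12 and 5), TGF-beta (6 and 10), proteasome (1 and 14), decay factors (7 and 18), RNA polymerase II (3 and 16) and respiratory chain (0 and 13), and were the same for the other lists. The largest edgeR adjusted p of a gene named in this comparison was 9.03e-14 (PLK1).

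The time effect in a tagged line, taken as its change from 2 h to 8 h minus that of the parental line, removes constant differences between lines. In the CNOT1-AID line, DNA replication and colon identity genes fell as lists. YAP/TEAD and immediate early genes fell with the preset correlation, but not with an estimated one (camera adjusted p = 0.0989 and 0.312), and ribosome biogenesis, zinc finger and heat shock genes rose on the same terms (0.14, 0.145 and 0.14). The largest falls included PAPPA (−5.48 ± 0.56) and FOS (−4.32 ± 0.25), and the largest rises included HPCAL4 (5.28 ± 0.61). In all 4655 genes were higher and 4963 lower. With S. pombe scaling 5955 were higher and 2206 lower, and with library size alone 5943 and 4107. G1/S genes fell in 38 and rose in 1 of 43 cases (median −0.73, camera adjusted p = 8.63e-13, and adjusted p = 0.0139 with an estimated correlation), with POLA1 at −1.30 ± 0.07. Colon identity genes fell in 16 and rose in 1 of 21 (median −0.79, adjusted p = 2.16e-09, and adjusted p = 0.0139 with an estimated correlation), with TSPAN8 at −3.88 ± 0.12. Ribosome biogenesis genes rose in 46 of 50 and fell in 0 (median 0.43, adjusted p = 3.88e-10, but adjusted p = 0.14 with an estimated correlation). YAP/TEAD targets fell in 13 and rose in 1 of 18 (median −0.99, adjusted p = 2.98e-09, but adjusted p = 0.0989 with an estimated correlation). ZNF-numbered genes rose in 199 and fell in 24 of 386 (median 0.42, adjusted p = 9.71e-09, but adjusted p = 0.145 with an estimated correlation). Immediate early genes fell in 22 and rose in 6 of 38 (median −0.48, adjusted p = 3.53e-07, but adjusted p = 0.312 with an estimated correlation), with EGR1 at −3.50 ± 0.08. ATF4 targets fell in 17 and rose in 3 of 25 (median −0.51, adjusted p = 5.98e-05, but adjusted p = 0.367 with an estimated correlation), and cholesterol genes fell in 18 and rose in 1 of 24 (median −0.57, adjusted p = 5.98e-05, but adjusted p = 0.145 with an estimated correlation). TGF-beta targets fell in 11 and rose in 1 of 18 (median −0.87, adjusted p = 9.95e-05, but adjusted p = 0.312 with an estimated correlation). Heat shock genes rose in 12 of 19 and fell in 0 (median 0.47, adjusted p = 0.000163, but 0.14 with an estimated correlation). Histone genes rose in 22 of 39 and fell in 0 (median 0.32, adjusted p = 0.000206, but 0.638 with an estimated correlation). RNA polymerase II genes rose in 22 and fell in 4 of 40 (median 0.27, adjusted p = 0.00213, but 0.0989 with an estimated correlation). Wnt targets fell in 11 and rose in 4 of 20, with a median of −0.31 that S. pombe scaling turned to 0.02 (adjusted p = 0.00213, but 0.182 with an estimated correlation), with LGR5 at −2.18 ± 0.07. Non-coding host genes rose in 12 and fell in 2 of 21 (median 0.34, adjusted p = 0.00368, but 0.312 with an estimated correlation). Unfolded protein response genes fell in 12 and rose in 1 of 20 (median −0.37, adjusted p = 0.00746, but 0.445 with an estimated correlation). Aryl hydrocarbon receptor targets fell in 6 and rose in 2 of 10 (median −0.44, adjusted p = 0.0186, but 0.418 with an estimated correlation). Counts adjusted over the list alone, higher and lower, differed for G1/S (2 and 38), colon (1 and 17), ZNF (201 and 25), immediate early (7 and 23), histones (23 and 0), RNA polymerase II (22 and 5) and Wnt (5 and 11), and were the same for the other lists. Of the genes named in this comparison, HPCAL4 had the largest edgeR adjusted p (1.99e-09).

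In the CNOT4-AID line the time effect was smaller, with 694 genes higher and 1446 lower. With the preset correlation of camera, the list of ATF4 targets was shifted up (12 of 25 rose) and those of YAP/TEAD, ribosomal protein, DNA replication and heat shock genes were shifted down (9 of 18, 15 of 77, 10 of 43 and 9 of 19 fell). Under an estimated correlation 0 lists passed (adjusted p = 0.0659 to 0.531 for these lists). S. pombe scaling left 37 genes higher and 155 lower, whereas library size alone gave 1815 and 549, and the count of 2140 changed genes dropped to 1404 without parental 2 h replicate 1. The glycosyltransferase gene GALNT18, on chromosome 11, fell (−2.10 ± 0.07), and the growth regulator gene DDIT4 rose (1.83 ± 0.14). ATF4 targets rose in 12 of 25 cases and fell in 0 (median 0.26, camera adjusted p = 2.01e-16, but 0.142 with an estimated correlation), with CHAC1 at 1.55 ± 0.20. YAP/TEAD targets fell in 9 of 18 and rose in 0 (median −0.42, adjusted p = 1.27e-14, but 0.0659 with an estimated correlation). Ribosomal protein genes fell in 15 of 77 and rose in 0 (median −0.14, adjusted p = 4.18e-07, but 0.531 with an estimated correlation), and ZNF-numbered genes rose in 59 and fell in 11 of 386 (median 0.17, adjusted p = 4.18e-07, but 0.24 with an estimated correlation and 0.0541 outside chromosome 19). G1/S genes fell in 10 of 43 and rose in 0 (median −0.13, adjusted p = 3.94e-06, but 0.0659 with an estimated correlation). Heat shock genes fell in 9 of 19 and rose in 0 (median −0.24, adjusted p = 1.8e-05, but 0.142 with an estimated correlation). Unfolded protein response genes fell in 9 of 20 and rose in 0 (median −0.26, adjusted p = 1.8e-05, but 0.321 with an estimated correlation). Cholesterol genes fell in 10 of 24 and rose in 0 (median −0.22, adjusted p = 2.69e-05, but 0.188 with an estimated correlation). Hypoxia genes fell in 8 and rose in 1 of 24 (median −0.21, adjusted p = 0.000506, but 0.175 with an estimated correlation). Adjusted over the list alone, the counts higher and lower were 15 and 1 (ATF4), 0 and 11 (YAP/TEAD), 0 and 27 (ribosomal proteins), 71 and 11 (ZNF), 0 and 15 (G1/S), 1 and 10 (heat shock), 1 and 10 (unfolded protein response), 0 and 11 (cholesterol) and 1 and 12 (hypoxia). The largest edgeR adjusted p of a gene named in this comparison was 3.14e-07 (CHAC1).

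**Figure D5:**
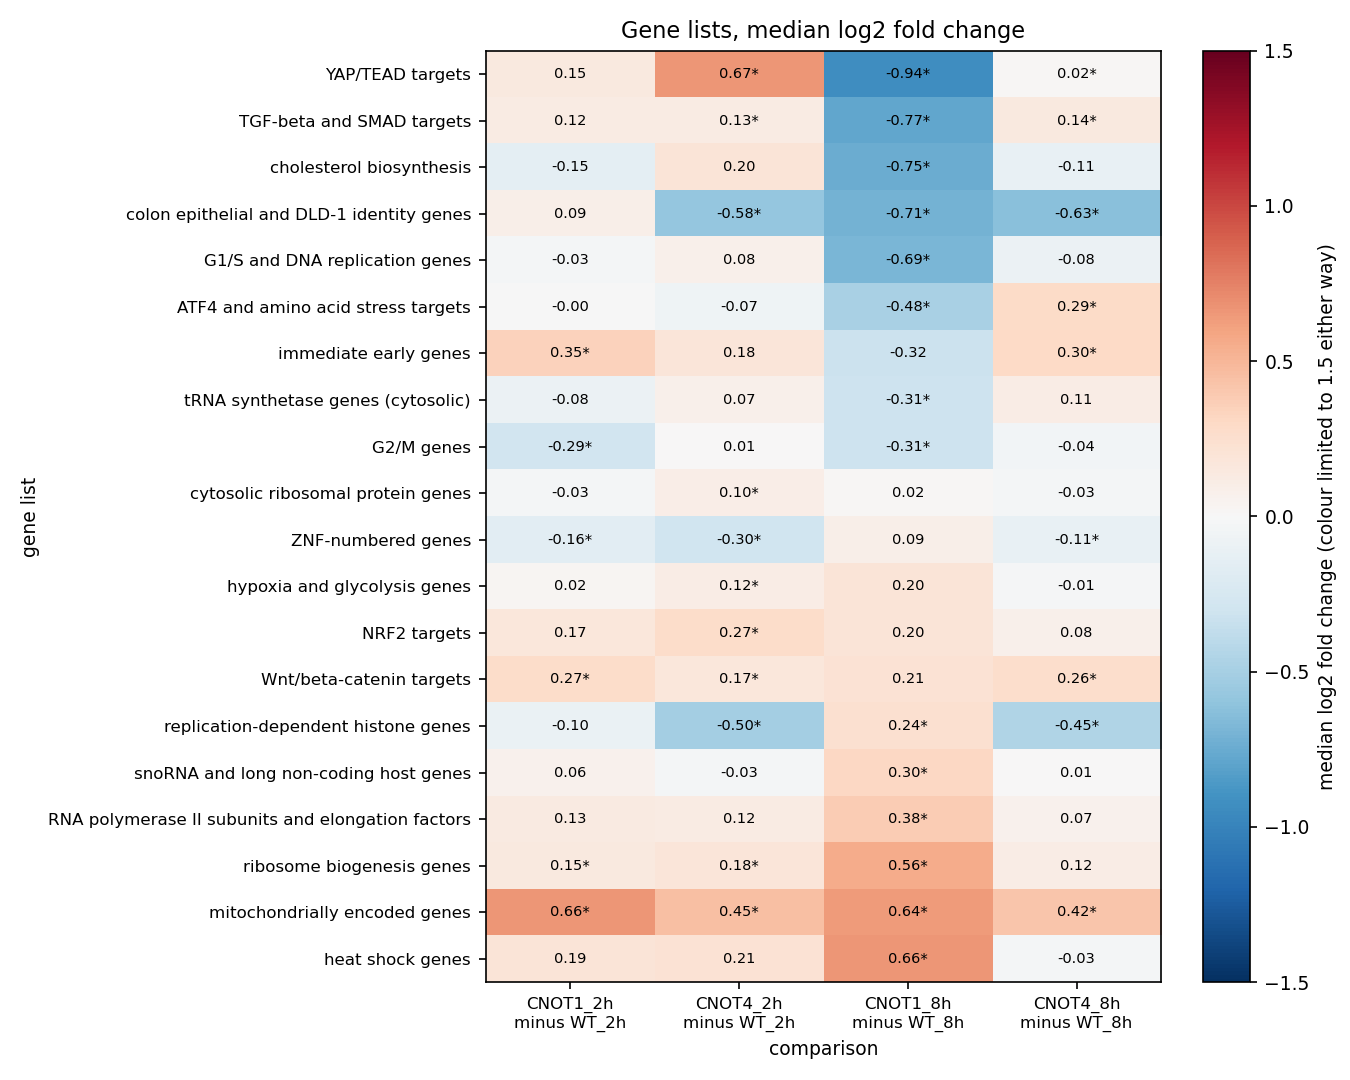
Median log2 fold change (colour, limited to 1.5 either way, and printed value) of fixed gene lists (vertical axis) in the 4 comparisons of a tagged line with the parental line (horizontal axis), with TMM scaling, for lists past camera in at least 1 of them. An asterisk marks a camera adjusted p under 0.05 with the preset correlation; ribosome biogenesis genes run from 0.115 in the CNOT4-AID line to 0.56 in the CNOT1-AID line after 8 h, and S. pombe scaling or library size alone turns the sign of some medians near 0.

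Effects were compared between the tagged lines across genes, which are not independent replicates. After 2 h, log2 fold changes of the 2 lines against the parental line correlated with Pearson r = 0.615 and a Spearman coefficient of 0.476 over 19916 genes, with a covariance of 0.437. Simulated unchanged groups against the same parental libraries gave r = 0.51, a Spearman coefficient of 0.451 and a covariance of 0.0350 (mean of 20 draws). After 8 h the values were r = 0.441, a Spearman coefficient of 0.322 and covariance 0.45, against simulated values of 0.504, 0.446 and 0.0333. Simulated groups held no changed gene, so their coefficients and counts are no baseline. Their covariances measure shared parental noise alone. After 2 h, 1905 genes were higher in both lines (741 if the lists were independent, 0.15 simulated), 1813 lower in both (677 and 0.05) and 735 changed in opposite directions. After 8 h the counts were 1726 (1076), 2281 (1207) and 1443, with 0 simulated in either shared direction. Set against 1 parental library each, both ways, an alternative chosen after seeing the data, the lines correlated at 0.417 and 0.424 after 2 h (covariance 0.391 and 0.394) and at 0.346 and 0.349 after 8 h (0.424 and 0.429). Between the times, which use different parental libraries, Pearson and Spearman coefficients were 0.529 and 0.427 for the CNOT1-AID line, and 0.755 and 0.579 for the CNOT4-AID line. In the CNOT1-AID line 2450 genes were higher at both times (1275 if independent), 2533 lower (1236) and 1164 opposite, and in the CNOT4-AID line 2107 (626), 2241 (661) and 199.

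Annotated classes were compared with protein-coding genes, long non-coding RNAs first. In the CNOT1-AID line after 8 h, 979 of 5515 rose and 1983 fell (odds ratio of rising over falling 0.404, Fisher's exact adjusted p = 3.16e-98). After 2 h 448 rose and 820 fell in the CNOT1-AID line (0.455, adjusted p = 2.81e-35), and 503 and 901 in the CNOT4-AID line (0.461, adjusted p = 6.79e-37). In the CNOT4-AID line after 8 h, 643 rose and 665 fell (1.09, adjusted p = 0.226). In the parental line 784 rose and 400 fell between the times (2.17, adjusted p = 9.28e-32). The odds ratio was 0.363 for the time effect in the CNOT1-AID line (adjusted p = 4.9e-76) and 4.17 in the CNOT4-AID line (adjusted p = 6.23e-24). Between the tagged lines it was 1.11 after 2 h (adjusted p = 0.117) and 0.348 after 8 h (adjusted p = 1.13e-125). Pseudogenes (565 tested) had an odds ratio of 0.327 in the CNOT1-AID line after 8 h (adjusted p = 4.78e-13), 0.349 after 2 h (adjusted p = 7.45e-05), 0.582 in the CNOT4-AID line after 2 h (adjusted p = 0.0412) and 2.28 in the parental line over time (adjusted p = 0.0103). These tests treat genes as independent.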

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

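The tests of contiguous DNA, of reads moving between genes and of matched gene properties were planned before their results were seen, and the other tests of explanations in this part were chosen afterwards.

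Effects differed between groups in direct tests with edgeR. Between the CNOT1-AID and CNOT4-AID lines 7218 genes differed after 2 h and 12889 after 8 h. The difference from the parental line changed between 2 h and 8 h for 9618 genes in the CNOT1-AID line and 2140 in the CNOT4-AID line. Of these, 1163 genes in the CNOT1-AID line and 198 in the CNOT4-AID line passed the threshold at both times in opposite directions.

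Of 386 ZNF-numbered genes 57 were over 4-fold lower and past the threshold in both tagged lines after 2 h, and 48 of these lie on chromosome 19. Members with at least 20 counts left showed no loss still in progress. Between the times their difference rose by a median of 0.62 in the CNOT4-AID line (95% interval 0.518 to 0.809, 22 genes). It rose by 0.35 in the CNOT1-AID line (0.051 to 0.642, 26 genes). Choosing members by low 2 h values favours a rise, so this cannot exclude such a loss. Other ZNF-numbered genes as a set gained none of the lost CPM. The highest share over 8 pairings of a tagged and a parental library was −29.3%, a further loss. Their own fall could hide moved reads and other similar genes were not counted, so read movement stays open. Loss of contiguous DNA stays open: 18.5% of 65 protein-coding neighbours within 100 kb were as low (9.92 to 30.03). But 37 of these neighbours are ZNF-numbered and could not count by construction. Of the other 28 neighbours 42.9% were as low (24.5 to 62.8). These 12 low neighbours include zinc finger genes with ZFP symbols and loci without a symbol, so 42.9% is not a share of unrelated genes. With 48 of the 57 genes still over 4-fold lower and past the threshold in both lines after 8 h, a fixed difference between the lines and a fast, lasting effect of depletion cannot be told apart, because no tagged line without auxin was analysed here.

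Chromosome 11 genes were higher in the CNOT4-AID line at both times. The properties of these genes are argued against as the cause by genes of other chromosomes matched on level, span and GC content, whose median was 0.015 (−0.011 to 0.039). A few strong genes could not move a median, so the 80.9% of genes lying above 0 describe the pattern and are no separate test. Extra copies of most of the chromosome in this line are a candidate explanation: both arms were higher (0.265 on the short arm after 2 h, the lowest arm value) and the change over time was −0.011. DNA was not measured, and an effect of depletion on a single chromosome was not tested.

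The human to S. pombe ratio was higher in both tagged lines at both times. Mitochondrial RNA is argued against by the lowest fold of 1.19 without mitochondrial and rRNA counts. Chance spread between libraries stays open: an exact two-sided permutation of line labels within times gave p = 0.00444 (fold 1.34), the smallest the 225 arrangements can give, but the separation of the libraries that drew attention fixes that value. A different amount of spike-in per amount of RNA between the lines cannot be told apart from more labelled RNA (largest fold 1.455), since both shift all genes by a factor per library. More labelled RNA per cell was not tested.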

How the results depend on the processing

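The alternatives without chromosome 11, without list members on chromosome 11, with ZNF genes outside chromosome 19 and with split parental libraries were chosen after the results were seen.

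Directions and calls of the larger effects held under most alternatives: of the values of named genes 362 kept direction and side of the threshold under the DESeq2 Wald test, 364 under limma-voom and 335 under S. pombe scaling, where 21 lost significance and 8 changed sign. Reversals below are of values near 0 unless S. pombe scaling or library size alone is named, which each add 1 shift per comparison to all genes; for the others the cause was not tested. Genes at low counts limit precision, and leaving out a library leaves 1 library in its group, which is assumed to vary like the other groups.

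With a log2 fold change over 1 as well, the stricter criterion left 1310 (CNOT1-AID, 2 h), 1746 (CNOT4-AID, 2 h), 5324 (CNOT1-AID, 8 h), 1425 (CNOT4-AID, 8 h), 1434 and 4862 (between the tagged lines, 2 h and 8 h), 877 (parental line over time), 3483 and 167 (time effects in the CNOT1-AID and CNOT4-AID lines) changed genes. S. pombe scaling gave 4666 between the tagged lines after 2 h, 4521 in the parental line over time and 192 for the time effect in the CNOT4-AID line. DESeq2 called 5926, 6027, 11586, 5068, 5779, 11212, 5789, 7832 and 1810 genes in the same order of comparisons.

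S. pombe scaling put CNOT1 at 0.113 (CNOT1-AID, 2 h), 0.457 (CNOT4-AID, 2 h, now past the threshold), 0.104 (CNOT1-AID, 8 h), 0.264 (CNOT4-AID, 8 h) and 0.103 (parental line over time). It put CNOT10 at 0.093 (CNOT1-AID, 2 h), CNOT4 at 0.259 and CNOT6L at 0.266 (CNOT4-AID, 8 h), and CNOT4 at −0.148 (between the tagged lines, 2 h). Library size alone put CNOT4 at 0.05 (CNOT1-AID, 2 h, no longer past the threshold), −0.031 (CNOT4-AID, 2 h) and −0.003 (parental line over time), and CNOT1 at −0.09 (CNOT4-AID, 2 h) and 0.048 (time effect, CNOT4-AID).

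In the CNOT4-AID line after 8 h, CNOT1, CNOT4 and CNOT6L were 0.009, 0.005 and 0.013 with no filter, 0.005, 0.001 and 0.009 without mitochondrial and small structural RNA genes, and 0.015, 0.011 and 0.019 without chromosome 11. CNOT1 and CNOT6L were 0.002 and 0.006 with protein-coding genes alone and 0.001 and 0.005 with only the groups compared. That last setting gave CNOT4 0.128 in the CNOT4-AID line after 2 h (no longer past the threshold). CNOT4 was −0.005 in the parental line over time with no filter, and between the tagged lines after 2 h −0.002 without chromosome 11 and 0 with DESeq2.

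Of 106 list calls 11 held with an estimated correlation, and the cause was not tested: 2, 2, 3, 1, 1, 0, 0, 2 and 0 in the order of comparisons above. Fry, which does not compare a list with other genes, called 24, 26, 31, 19, 22, 33, 28, 27 and 17, and it also ended the calls of mitochondrially encoded genes in the parental line over time (0.0713) and of ribosomal protein genes for the time effect in the CNOT4-AID line (0.121). Library size alone left 6 lists in the CNOT4-AID line after 2 h.

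Leaving out each library gave CNOT1 −0.126 to −0.109 and CNOT4 0.103 to 0.172 (CNOT1-AID, 2 h), CNOT4 0.093 to 0.165 (CNOT4-AID, 2 h), −0.034 to 0.035 (parental line over time) and −0.012 to 0.04 (between the tagged lines, 2 h), and CNOT1 −0.023 to 0.011 and CNOT6L −0.021 to 0.009 (CNOT4-AID, 8 h). The time effect in the CNOT4-AID line ranged from 1404 genes (without parental 2 h replicate 1) to 1932, and from 9 to 15 lists. Correlations ranged from 0.5461 to 0.6863 and 0.4068 to 0.4978 between the lines (2 h, 8 h; 0.4169 and 0.4242, and 0.3456 and 0.3493, with 1 parental library for each line, fits that test more low-count genes), and from 0.4734 to 0.523 (CNOT1-AID) and 0.6923 to 0.727 (CNOT4-AID) between the times. With log2 CPM over 3 the last were 0.5887 and 0.9049. Without S. pombe rRNA and human mitochondrial counts the log2 spike-in ratio of the CNOT1-AID line after 8 h was 0.4656.

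With the replicate number as a block the counts were 7409, 7428, 13270, 6738, 7135, 12818, 7162, 9546 and 2090. The numbers do not pair the libraries, since deviations of same-numbered libraries correlated at −0.169 to 0.31 over 15 pairs of groups, 2 of them above 0.1, and the block ended no list call and 1 call of a gene eligible to be named.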

Other observations

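The test in this part was planned before its result was seen.

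Several fixed lists did not pass camera in any comparison of a tagged line with the parental line. In the order CNOT1-AID 2 h, CNOT4-AID 2 h, CNOT1-AID 8 h and CNOT4-AID 8 h, the counts of members higher and lower were 13 and 10, 17 and 7, 22 and 14, and 13 and 7 for 44 other cytoplasmic mRNA decay factors, and 5 and 2, 8 and 1, 9 and 3, and 1 and 1 for 18 nuclear exosome genes. They were 8 and 1, 5 and 5, 7 and 8, and 1 and 2 for 20 NF-kB targets, 4 and 6, 4 and 6, 11 and 7, and 7 and 7 for 23 p53 targets, and 5 and 8, 10 and 9, 12 and 10, and 7 and 8 for 30 interferon-stimulated genes. Unfolded protein response genes (20) gave 7 and 0, 7 and 1, 2 and 11, and 3 and 9, and aryl hydrocarbon receptor targets (10) 8 and 1, 4 and 2, 3 and 6, and 6 and 2. The counts adjusted over the list alone were 16 and 10, then 17 and 8 for decay factors after 2 h, 9 and 2 (CNOT4-AID, 2 h) and 0 and 0 (CNOT4-AID, 8 h) for exosome genes, 6 and 5 for NF-kB and 7 and 2 for unfolded protein response genes (CNOT4-AID, 2 h), and 8 and 2, 7 and 2, and 7 and 2 for receptor targets except after 8 h in the CNOT1-AID line. They were otherwise the same.

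Of 34 transposon silencing factors 11 and 6, 9 and 6, 16 and 14, and 4 and 10 were higher and lower, of 26 polycomb genes 14 and 3, 9 and 2, 13 and 8, and 6 and 3, and of 27 autophagy genes 3 and 8, 6 and 2, 12 and 7, and 4 and 4. Respiratory chain genes (66) gave 8 and 8, 11 and 4, 32 and 8, and 7 and 8, proteasome genes (34) 3 and 6, 8 and 4, 14 and 4, and 3 and 5, and snoRNA genes (9) 0 and 3, 1 and 2, 0 and 5, and 0 and 0. Markers of other cell types gave 4 and 1, 4 and 2, 4 and 3, and 3 and 2 for fibroblasts (9), 0 and 1, 0 and 1, 1 and 1, and 1 and 2 for leukocytes (6), 0 and 2, 1 and 3, 2 and 3, and 1 and 3 for endothelium (6), and 1 and 1, 1 and 2, 3 and 1, and 1 and 2 for neurons (6). Germline genes (7) gave 0 and 0, 1 and 1, 1 and 3, and 0 and 2, and early embryonic genes (4) 1 and 1, 1 and 1, 2 and 0, and 1 and 1. With p adjusted over the list alone, polycomb genes gave 10 and 3 (CNOT4-AID, 2 h) and 6 and 4 (CNOT4-AID, 8 h), respiratory chain genes 6 and 6, 9 and 4, and 6 and 8 except after 8 h in the CNOT1-AID line, proteasome genes 2 and 6 (CNOT1-AID, 2 h), endothelial markers 1 and 2 (CNOT1-AID, 2 h) and 2 and 4 (CNOT1-AID, 8 h), germline genes 0 and 1 (CNOT4-AID, 8 h), and the other counts were the same.

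Fold changes in the CNOT1-AID line after 8 h fell with the genomic span of the gene (Spearman −0.221 over protein-coding genes with a position, across genes, which are not independent replicates). The median log2 fold change went from 0.323 for 2241 genes of up to 10 kb to −0.223 for 694 genes over 300 kb. The correlation was −0.117 in the CNOT4-AID line after 8 h, set against the same parental libraries, −0.0773 in the CNOT1-AID line after 2 h and 0.188 in the parental line over time. A change of the parental line alone was tested as the explanation with the change from 2 h to 8 h within the CNOT1-AID line, where the correlation was −0.1104 (95% interval −0.126 to −0.0935, 13528 genes). The interval lies below the value that this explanation needed, but its upper end does not reach the bound set beforehand against it, so by that bound the explanation was not excluded.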
